A study of Mus musculus with 2 samples.

How the data were processed

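Splenic T cells of C57BL/6 mice infected with lymphocytic choriomeningitis virus (LCMV) Clone 13, a strain that causes chronic infection, were profiled by droplet single-cell RNA sequencing (10x Genomics Chromium, 3′ chemistry). The labels describe the cells as flow-sorted CD8 T cells that carried CD44 and bound the gp33 reagent, so they recognised a peptide of the viral glycoprotein. There was 1 library from day 8 and 1 library from day 30 after infection. How many mice were pooled is not given in the sources used here.

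Both libraries came as whole-number UMI counts per gene and cell barcode, as the authors deposited them, and no normalization had been applied to them. The matrices were made with Cell Ranger 1.3.1 on the mm10 genome build per the submitters' processing notes. Each holds 27998 genes, with 1940 barcodes on day 8 and 1838 on day 30. The rule used upstream to keep barcodes is not given in the sources used here, and the lowest totals seen were 1494 and 822 UMIs per barcode.

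Barcodes were kept with at least 500 genes detected, under 10% of UMIs from mitochondrial genes, and UMIs from fewer than 3 genes of any one of the B cell, myeloid and erythroid marker lists. This left 1888 cells on day 8 and 1825 on day 30. The mitochondrial limit removed 40 and 8 barcodes, myeloid markers 13 and 4, B cell markers 1 and 0, erythroid markers 0 and 1, and the gene minimum 0 and 3. Some barcodes failed more than 1 limit, so 52 and 13 were removed. Doublets were kept. Scrublet, at an expected rate of 2%, called 1 and 8 cells, and the values without them are among the alternatives.

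UMIs were summed over the kept cells of a library and divided by the library total to give CPM, which sets both libraries to a common total. With 1 library per day there was no replicate check and no test between days or cell classes. Cells are not replicates, so no p-value was made from cells. Each gene's ratio has an exact conditional binomial 95% interval, each share of cells an exact Clopper-Pearson 95% interval, and all of these cover counting error only. A gene with 0 counts was set against a floor of 3 counts, equal to 0.228 CPM on day 8 and 0.419 CPM on day 30.

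Gene lists were fixed before the data were examined: 18 program lists and 12 marker lists, together 337 genes, of which 8 are not in the annotation used. A member counted as measured with at least 10 CPM on 1 side of a comparison. The median log2 ratio of a list was set against 10000 random lists of the same size, matched on mean expression in 20 bins. This percentile describes these libraries and is no test. In simulated counts, 200 of 6991 genes were given a change. Of 400 lists of 14 unchanged genes, 4.50% fell outside the central 95% of 1000 random lists. Of the gene intervals, 95.1% held the simulated ratio. The simulated counts varied by counting error alone and the lists were drawn at random, so this checks the computation only.

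For shares of cells with a UMI and for gates on detected transcripts, every cell was thinned at random to 2000 UMIs. This left out 16 cells of day 8 and 75 of day 30 as too shallow. Cells not seen to cycle were those without a UMI of the S phase and mitosis lists after this thinning, 373 on day 8 and 447 on day 30. These were 19.9% and 25.5% of the thinned cells, although Mki67 was seen in only 10.9% and 3.83%. The lists hold genes not confined to dividing cells: a day 30 cluster with 9.87 CPM of Mki67 held 114 of Slbp and 109 of Pcna. A cell outside this set therefore need not have been cycling. The comparison of the days among cells not seen to cycle used all of their UMIs.

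Each library was clustered on its own with Leiden in igraph 0.11.9: 1500 highly variable genes, values clipped at 10 after scaling, 20 principal components, 20 neighbours, resolution 0.8 and seed 0. Scanpy 1.11.5, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 under Python 3.11.15 did the rest. Genes of the fixed lists were left out of the clustering features, except the cell cycle, B cell, myeloid and erythroid lists. Ribosomal protein, mitochondrial and antigen receptor segment genes were left out too. The lists compared between clusters therefore did not define them. S phase and mitosis lists were among the features and were not compared between classes. Cluster names were rebuilt here from the fixed markers and are not the authors'. Naming markers were left out of list medians between classes.

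The rule for named genes took, for the days, the 12 highest and 12 lowest ratios among genes with at least 50 CPM in 1 library. It also took up to 4 members of each list with at least 20 CPM and the largest absolute ratios. Ribosomal, mitochondrial, antigen receptor, predicted and sex-linked marker genes were left out. Between classes it took up to 4 members per list with at least 50 CPM that name no class, in the same direction in each library compared. For the gates it took the 10 highest and 10 lowest genes with at least 50 CPM and the same direction in both libraries. Some genes that these rules name are not reported here. Gene positions come from GENCODE vM21, which may differ from the authors' annotation.

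Alternatives were another scaling (median-of-ratios size factors, or a total without ribosomal protein and mitochondrial genes), the mean of each cell's CPM, no cell filter, a filter of 1000 genes and 5% mitochondrial UMIs, Scrublet calls left out, cells not seen to cycle, and list minimums of 1 and 50 CPM. Others were thinning to 1000 or 3000 UMIs or none, a gate of 2 UMIs, resolutions of 0.5 and 1.2, lists among the clustering features, and cycling genes out with cycle scores regressed out. Clusters of another clustering were not named anew from markers. Each took the main class that held over 50% of its cells, so a class there can hold cells of other main clusters. Leaving out the 5% of cells with the most UMIs, and leaving out a small cluster led by Ccr7 in each library, were chosen after seeing the data.

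The sort was checked with marker lists. All 1888 and 1825 kept cells had a UMI of a CD8 T cell marker. The members of that list in the annotation were Cd3d, Cd3e, Cd3g, Cd8a and Cd8b1. A UMI of any of them was enough, so this count does not tell CD8 T cells from other T cells. Of the day 8 cells, 1 had UMIs of at least 2 CD4 T cell markers, and 0 of the day 30 cells did. None had 3 NK cell markers: 0 cells on each day. Myeloid markers held 0.0229% of UMIs on day 8 and 0.0154% on day 30, B cell markers 0.00182% and 0.000741%, and erythroid markers 0.000312% and 0.00312%. Most of these UMIs came from genes that were also high within T cell clusters: Cst3 gave 2786 and 995 of the 3014 and 1103 myeloid UMIs, and Car2 gave 201 of the 223 erythroid UMIs on day 30. The gamma-delta T cell list gave no reading, since Sox13 was its 1 member in the annotation and had 0 UMIs on both days.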

Results

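The data are 2 single-cell libraries of virus-specific CD8 T cells from the spleen, 1 taken on day 8 and 1 on day 30 after infection with LCMV Clone 13. By its title, the study asks whether help from CD4 T cells shapes a killer subset of CD8 T cells, set apart by its transcripts, when infection persists. No library from mice lacking CD4 T cells is analysed here, so the comparisons concern the days and the kinds of cells within each day. Day 8 held 1888 cells and 13158042 UMIs, with medians of 6568.5 UMIs and 2102 genes per cell. Day 30 held 1825 cells and 7156743 UMIs, with medians of 3540 UMIs and 1452 genes. Malat1, a nuclear noncoding RNA, took 1.64% of UMIs on day 8 and 4.39% on day 30, and the 10 genes with the most UMIs took 10.3% and 14.6%. Without replicate libraries, differences are given as ratios with counting intervals and as higher or lower in these libraries. Day and library cannot be separated.

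The comparison of the days asks how the virus-specific population differed between an early and a late stage of chronic infection. The day 30 library was higher in natural killer type receptors, chemokines and exhaustion-associated transcription factors, and lower in genes of mitosis, glycolysis and oxidative phosphorylation. The highest ratio belonged to Klra9 (ENSMUSG00000033024), a Ly49 family receptor better known from natural killer cells, on chromosome 6 from 130178675 to 130193112. Its level was 1.98 CPM on day 8 and 145 CPM on day 30, a log2 ratio of 6.19 (95% interval 5.64 to 6.82). The lowest belonged to Ifitm1 (ENSMUSG00000025491), an interferon-induced membrane protein gene on chromosome 7 from 140967221 to 140969825. It went from 57.1 CPM to 2.10 CPM, a log2 ratio of -4.77 (-5.61 to -4.04). Across 7424 genes with at least 10 CPM in 1 library the median log2 ratio was 0.11.

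Among killer cell lectin-like receptors, 6 of 8 measured members had a higher CPM on day 30, and the list median was 0.75 against a central 95% of random lists from -0.36 to 0.34. Members are counted as higher or lower by their ratio alone, unless an interval is named. Klre1 held 17.1 CPM on day 8 and 184 CPM on day 30, with a log2 ratio of 3.42 (3.22 to 3.64). Klra3 and Klrc2, a Ly49 and an NKG2 family receptor, had log2 ratios of 1.27 and 1.03. In the cytokine and chemokine list 5 of 7 members were higher (median 0.61, random lists -0.46 to 0.32). Xcl1, which attracts cross-presenting dendritic cells, went from 22.5 to 149 CPM, a log2 ratio of 2.73 (2.54 to 2.92). The inflammatory chemokines Ccl5, Ccl4 and Ccl3 had log2 ratios of 1.38, 1.21 and 0.61. Ccl5 alone took 34763 CPM on day 30.

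Exhaustion-associated transcription factors had the highest median of the program lists, 1.27 (random lists -0.30 to 0.35), with 9 of 10 members higher. Tox2, Maf, Eomes and Nr4a2 had log2 ratios of 1.91, 1.92, 1.90 and 1.82. Tox2 belongs to the family of Tox, a factor known to maintain exhausted T cells, and Nr4a2 is induced by antigen receptor signalling. In the effector transcription factor list 9 of 10 members were higher and the median was 0.43 (random lists -0.31 to 0.31). Zeb2, a repressor tied to terminal effector differentiation, went from 66.6 to 271 CPM, a log2 ratio of 2.03 (1.91 to 2.14). Prdm1 (Blimp-1) and Runx3 had log2 ratios of 1.05 and 0.98, and Irf8 was lower at -0.98. That list was inside the random range among cells not seen to cycle (0.32) and among members with at least 50 CPM (0.22). Memory and stem-like transcription factors had a median of 0.28, inside the random range, with Klf3 at 1.82, Zfp36l2 at 0.81, Lef1 at -0.97 and Satb1 at -1.37.

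The cytolytic granule list showed no common direction: 6 of 13 members were higher and 7 lower, its median was -0.03 and its mean 0.23. Gzma, a granule protease, went from 861 to 3764 CPM, a log2 ratio of 2.13 (2.10 to 2.16). The death ligand Fasl had a log2 ratio of 1.92 and Gzmk one of 1.12. Serpinb6b, a serine protease inhibitor, was lower at -1.09. Granzyme B, encoded by Gzmb, lay outside the rule for named genes and was chosen after its values were seen: it went from 1438 to 1001 CPM, a ratio of -0.52 (-0.56 to -0.48). Inhibitory receptors were mixed too, with a median of 0.05: of 12 members, the interval lay above 0 for 4, below 0 for 4 and included 0 for 4. Cd244, a SLAM family receptor, went from 9.35 to 73.9 CPM, with a log2 ratio of 2.98 (2.70 to 3.28). Entpd1, an ectonucleotidase, had a log2 ratio of 1.42, and Pdcd1, which encodes PD-1, went from 93.8 to 142 CPM with a ratio of 0.60 (0.48 to 0.72). Havcr2, which encodes TIM-3, was lower at -0.33.

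Genes of migration went both ways, with 9 of 19 homing and adhesion members higher and a median of -0.10. S1pr5, a sphingosine-1-phosphate receptor, went from 6.54 to 97.1 CPM, a log2 ratio of 3.89 (3.57 to 4.23). Cx3cr1, the fractalkine receptor, went from 125 to 292 CPM, with a ratio of 1.23 (1.13 to 1.32), and Cxcr4 had a ratio of 1.34. Ccr2, a receptor for inflammatory chemokines, went from 111 to 29.2 CPM, with a ratio of -1.93. Cytokine receptors had a median of 0.15 and a mean of -0.01: Il21r and Il10ra had log2 ratios of 1.25 and 0.67, while Il18r1 and Ifngr1 were lower at -1.45 and -0.93. Among apoptosis regulators (median -0.02) the survival gene Bcl2 had a log2 ratio of 1.10 and the effector Bak1 one of -0.73. Costimulatory receptors had a median of 0.11, with Tnfrsf9 at 0.71 and Icos at -0.53. Outside the lists, Cd7, Rgs1, Prss2, Ptger4 and Serpina3g were among the highest ratios, at 3.41, 2.43, 6.12, 2.10 and 2.10. Cd7 is a receptor of T and natural killer cells and Rgs1 dampens chemokine receptor signalling. Plac8, the metallothionein Mt1, the actin-capping protein gene Capg and AA467197 were among the lowest, at -1.96, -1.96, -1.90 and -2.86.

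Of 14 measured members of the mitosis list, 13 had an interval below 0 and 1 an interval that included 0, with a median of -1.70 (random lists -0.18 to 0.38). Ube2c, which encodes the ubiquitin-conjugating enzyme of the anaphase-promoting complex, went from 73.6 to 13.6 CPM, a log2 ratio of -2.44 (-2.76 to -2.14). Birc5, Ccnb2 and Cenpe had log2 ratios of -2.04, -1.98 and -1.95. The further cell cycle genes Cdca3 and Cks1b had ratios of -2.31 and -2.06. DNA replication genes had a median of -0.28 with 11 of 16 members lower, among them Tk1 at -1.21 and Dut at -0.59. With members of at least 50 CPM alone that median was -0.06, inside the random range. In the glycolysis list 13 of 15 members were lower (median -0.38, random lists -0.26 to 0.30), with Pgk1, Ldha, Tpi1 and Gapdh at -1.19, -0.94, -0.94 and -0.91. In the oxidative phosphorylation list 35 of 36 members were lower (median -0.41, random lists -0.29 to 0.02), with Cox5a and Atp5g3 both at -0.81 and Cox5b and Ndufb9 at -0.68 and -0.65.

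Immediate early and heat shock genes had a median of 0.50 (random lists -0.28 to 0.31), with 11 of 13 members higher. Ier5, the phosphatase gene Dusp1 and the AP-1 genes Fos and Junb had log2 ratios of 1.94, 1.54, 1.38 and 1.17. In the interferon-stimulated gene list 20 of 23 members were higher and the median was 0.35 (random lists -0.17 to 0.28), with Rsad2, Ifit1, Isg15 and Ddx58 at 0.93, 0.80, 0.76 and 0.70. This median fell within the random range with the mean of per-cell CPM (0.30), among cells not seen to cycle (0.17) and among members with at least 50 CPM (0.15). The 8 interferon-stimulated markers had a median of 0.65, and 0.42 with the mean of per-cell CPM, inside the random range. MHC class I antigen presentation genes were inside the random range at 0.06, with H2-Q4 at 0.81 and Psmb9 at -0.45.

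Of the marker lists used to name cells, the CX3CR1 effector markers had a median of 0.73 (random lists -0.40 to 0.37) and the proliferating markers one of -1.85 (-0.25 to 0.42). Of the 7 CX3CR1 effector markers, Ly6c2 and S1pr1 were lower, at -1.18 and -0.40, and the interval of Klrg1 included 0. Exhausted markers (0.33) and progenitor markers (0.12) were inside the random range, with Rgs16 at 0.68, Cxcr6 at -0.47 and Slamf6 at -0.47. With the mean of per-cell CPM the exhausted markers were at 0.46, outside the random range, and the progenitor markers at -0.31. The CD8 T cell markers had a median of 0.35 (random lists -0.57 to 0.28), with Cd3e at 0.60 and Cd3d at -0.39.

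**Figure D1:**
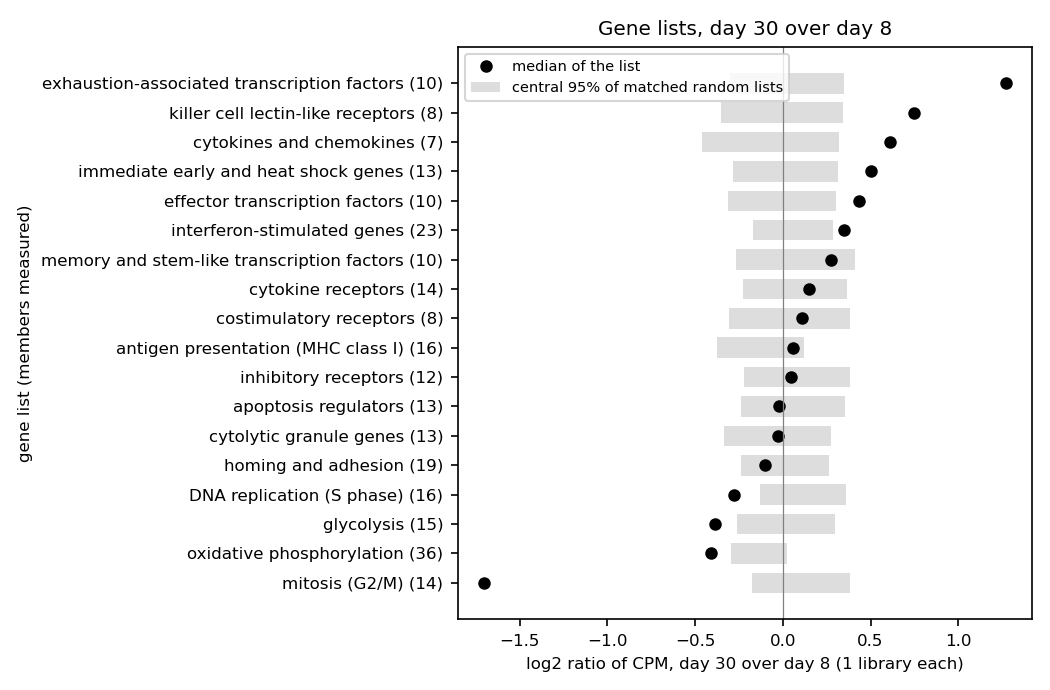
Median log2 ratio of CPM, day 30 over day 8, for each program list (black points, number of measured members in brackets), with the central 95% of 10000 matched random lists as grey bars. Exhaustion-associated transcription factors lie furthest right at 1.27 and mitosis genes furthest left at -1.70.

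Shares of cells with a UMI were compared after thinning every cell to 2000 UMIs, which kept 1872 cells of day 8 and 1750 of day 30. Cx3cr1 was seen in 19.7% of cells on day 8 (95% interval 17.9 to 21.5%) and 33.3% on day 30 (31.1 to 35.6%). In progenitor-like cells, taken as a background because they should lack it, the shares were 0.831% and 3.44%. Gzma was seen in 25.4% (23.4 to 27.4%) and 54.5% (52.1 to 56.9%) of cells, against 1.39% and 9.06% of progenitor-like cells. Gzmb was seen in 72.8% and 65.1%, against 7.48% and 5.63%. Havcr2 was seen in 10.3% (8.92 to 11.7%) and 7.31% (6.14 to 8.64%), against 1.11% and 0.312%. The median depth before thinning was 7120 and 4415 UMIs in progenitor-like cells.

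Tcf7, which encodes the progenitor factor TCF-1, was seen in 11.7% of cells on day 8 (10.3 to 13.2%) and 10.6% on day 30 (9.22 to 12.2%). Its share in CX3CR1 effector-like cells was 3.51% on both days. Slamf6, a surface marker of progenitor cells, was seen in 22.97% and 14.6%, against 14.6% and 2.73% of CX3CR1 effector-like cells. Il7r, the interleukin-7 receptor, was seen in 8.71% and 8.69%, against 5.26% and 0.780%. The CX3CR1 effector-like cells had median depths of 5684 and 3173.5 UMIs. On day 8 they held 75.8 CPM of Slamf6 and 43.2 of Il7r, against 13.4 and 4.65 on day 30. The day 8 shares of these genes in that class therefore need not be background. Pdcd1 was seen in 15.0% (13.4 to 16.7%) and 22.7% (20.7 to 24.7%) of cells, and Mki67, a marker of cycling cells, in 10.9% and 3.83%. A small cluster led by Ccr7, with median depths of 4012 and 5569 UMIs, served as their background. In it Pdcd1 was seen in 0 of 27 cells, which by the floor of 3 counts allows a share of up to 11.1% (exact upper limit 12.8%), and in 1 of 39 cells. Mki67 was seen in 0 of 27 and 0 of 39 cells, which by that floor allows up to 11.1% and 7.69% (exact upper limits 12.8% and 9.03%).

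Without thinning, when day 8 cells were the deeper ones, the shares were 38.6% and 41.2% for Cx3cr1, 37.3% and 61.5% for Gzma, and 81.8% and 73.1% for Gzmb. They were 23.5% and 17.5% for Tcf7, 44.8% and 21.8% for Slamf6, 19.1% and 12% for Il7r, 26.3% and 13.8% for Havcr2, and 23.3% and 7.18% for Mki67. For Pdcd1 they were 35.1% and 34.2%, the opposite order of the thinned shares. The Cx3cr1 intervals overlapped without thinning, those of Tcf7 and Il7r did not, and those of Havcr2 overlapped at 1000 and 3000 UMIs.

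**Figure D2:**
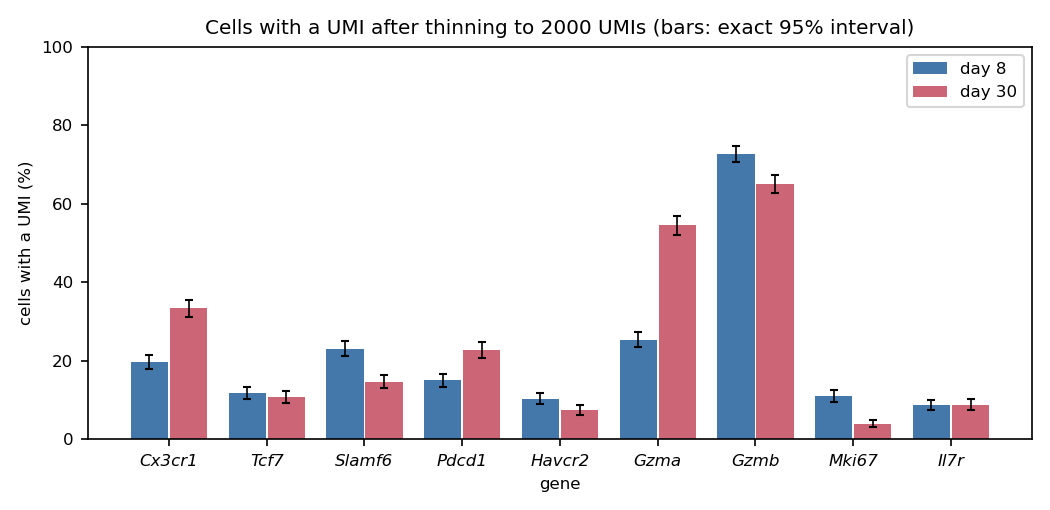
Percent of cells with at least 1 UMI of each gene after thinning to 2000 UMIs, for day 8 (blue) and day 30 (red), with exact 95% binomial intervals as bars. Gzma stands at 25.4% and 54.5%, and Cx3cr1 at 19.7% and 33.3%.

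Clustering each library on its own asks which kinds of cells the gp33-specific population held. Both libraries held a CX3CR1 effector-like cluster, a progenitor-like cluster and proliferating-like clusters, and an exhausted-like cluster was named on day 30 alone. The naming does not show that such cells were missing on day 8. On day 8, 517 of 1888 cells were CX3CR1 effector-like (27.4%, 25.4 to 29.5%), 365 progenitor-like (19.3%, 17.6 to 21.2%) and 414 proliferating-like (21.9%, 20.1 to 23.9%). On day 30, 530 of 1825 cells were CX3CR1 effector-like (29.0%, 27.0 to 31.2%), 484 exhausted-like (26.5%, 24.5 to 28.6%), 326 progenitor-like (17.9%, 16.1 to 19.7%) and 157 proliferating-like (8.60%, 7.36 to 9.98%). The libraries were clustered separately, so these shares stand side by side and are not compared. Shares depended on the clustering: at resolution 0.5 the CX3CR1 effector-like share was 50.8% on day 8 and the proliferating-like share on day 30 was 15.6%. Unnamed clusters held 160 cells on day 8 at that resolution, so cells unnamed in the main run took class names there. The day 30 proliferating-like share was between 1.33% and 5.01% in 4 other settings: lists among the features, cycling genes out with cycle scores regressed out, Scrublet calls left out, and the deepest 5% of cells left out. Unnamed clusters held 426, 137 and 29 cells on day 8 and 289 and 39 on day 30. The unnamed clusters of 137 and 289 cells were led by DNA replication genes. In the first of them only 3 cells were not seen to cycle, and it held 139 CPM of Mki67, so the proliferating-like shares do not count all cycling cells.

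Naming rested on the fixed markers. On day 30 the CX3CR1 effector-like cells held 826 CPM of Cx3cr1, 887 of Zeb2, 354 of S1pr5 and 210 of Klrg1, a receptor of short-lived effector cells, against 11.2, 28.2, 1.31 and 0.656 in the exhausted-like cells. Exhausted-like cells held 269 CPM of Pdcd1, 554 of Lag3, 318 of Cd160 and 512 of Cxcr6, against 40.1, 85.4, 33.1 and 131 in the CX3CR1 effector-like cells. None of these exhaustion markers was among the 10 genes that most set this cluster apart, and it was named from its levels. It was the highest of the day 30 clusters in 7 of the 8 exhausted markers, and in Havcr2 it held 74.8 CPM against 76.6 in an unnamed cluster led by replication genes. Progenitor-like cells held 262 CPM of Tcf7, 435 of Slamf6, 252 of Id3 and 667 of Xcl1 on day 30, and 342, 540, 234 and 71.5 on day 8. The day 8 CX3CR1 effector-like cells held 209 CPM of Cx3cr1, 130 of Zeb2 and 20.2 of S1pr5, together with 332 of Lag3 and 469 of Cxcr6. The unnamed day 8 cluster of 426 cells had Rgs16 and Havcr2 among its 10 leading genes. It was the highest of that day in Lag3 (427 CPM), Havcr2 (87.8), Rgs16 (54.5) and, by little, Entpd1 (26.2 against 26.1 in the CX3CR1 effector-like cells). It was left unnamed because it also held CX3CR1 effector markers, with 149 CPM of Cx3cr1 and 80.6 of Zeb2. These levels lay below those of the CX3CR1 effector-like cells and nearer those of the whole day 8 library, 125 and 66.6 CPM. The naming was uneven: this cluster had exhausted markers among its 10 leading genes, and the exhausted-like cluster of day 30 had none.

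**Figure D3:**
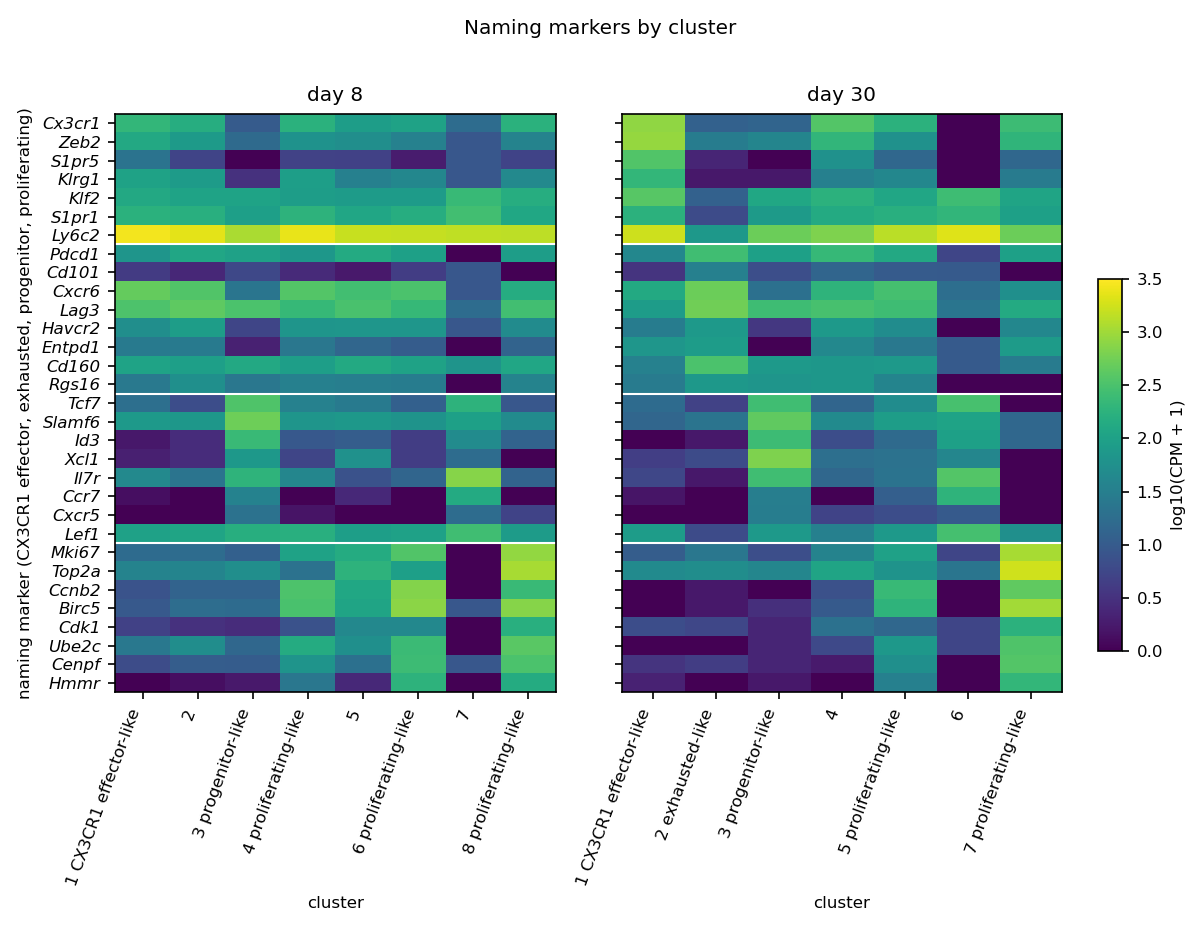
Level of each naming marker (rows, grouped as CX3CR1 effector, exhausted, progenitor and proliferating) in each cluster of day 8 (left) and day 30 (right), as log10 of CPM plus 1. On day 30 Cx3cr1 and S1pr5 are highest in cluster 1 and Pdcd1, Cd101 and Cd160 in cluster 2.

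The first contrast between classes asks how CX3CR1 effector-like cells differed from exhausted-like cells, which shared the day 30 library. The CX3CR1 effector-like cells were higher in killer cell lectin-like receptors and in several trafficking genes. Exhausted-like cells were higher in chemokines, inhibitory receptors and exhaustion-associated transcription factors. The cytolytic granule list separated neither class, with a median of 0.12 (random lists -0.27 to 0.26) and 7 of 13 members higher. All 8 lectin-like receptors were higher in the CX3CR1 effector-like cells, with a median of 3.79 (random lists -0.32 to 0.31). Klre1 held 630 CPM against 18.4 CPM, a log2 ratio of 5.10 (4.56 to 5.70), and Klra9 508 against 6.56, a ratio of 6.27. Klrk1, which encodes NKG2D, held 522 against 19.7 CPM, a ratio of 4.73. Memory and stem-like factors had a median of 1.24 (-0.45 to 0.42), led by Klf3 at 2.65, and homing and adhesion genes one of 0.55 (-0.28 to 0.25). In the latter Ccr2 had a log2 ratio of 5.57 (3.68 to 8.63, from 2 UMIs in the exhausted-like cells), Itgb1 and Itgb7 had ratios of 2.38 and 2.02, and the chemokine receptor Cxcr3 one of -3.68. The interleukin-18 receptor genes Il18rap and Il18r1 had ratios of 5.30 and 3.98, while the cytokine receptor list as a whole was at 0.02, with a mean of 0.79.

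The exhausted-like cells held more of 7 of the 8 measured cytokines and chemokines (median -1.62, random lists -0.39 to 0.40). Ccl4 held 852 CPM in the CX3CR1 effector-like cells and 2657 CPM in the exhausted-like cells, a log2 ratio of -1.64 (-1.73 to -1.55). Ccl3 and the lymphotoxin gene Ltb had ratios of -2.17 and -3.02, and Ifng, the interferon gamma gene, one of -0.06 (-0.26 to 0.14). Inhibitory receptors beyond the naming markers had a median of -2.13 (-0.64 to 0.49), with Ctla4 at -3.55 and Cd244 at -2.13. Exhaustion-associated factors had a median of -1.95 (-0.32 to 0.29), with Ikzf2, Maf, Nr4a2 and Eomes at -3.68, -3.02, -2.84 and -2.23. Costimulatory receptors had a median of -0.84 (-0.36 to 0.35), with Tnfrsf9, which encodes 4-1BB, at -4.21 and Cd27 at -1.58. MHC class I genes had a median of -0.31 (-0.20 to 0.20), with Tap1 at -0.76. Among cytolytic genes, Gzmk held 123 against 440 CPM, a ratio of -1.84, Fasl was at -0.64, and Serpinb9, an inhibitor of granzyme B, at 0.79. Effector factors were split between Tbx21, which encodes T-bet, at 1.64 and Runx3 at -1.20, with a list median of 0.14. Interferon-stimulated genes were inside the random range at -0.17, but outside it with the lists among the clustering features (-0.37) and without the deepest 5% of cells (-0.40). Apoptosis, glycolysis, oxidative phosphorylation and immediate early lists lay within 0.1 of 0, at -0.07, -0.05, -0.01 and -0.05. The mean of the glycolysis list was 0.15.

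CX3CR1 effector-like cells were next set against progenitor-like cells, a contrast that both libraries held. In both libraries the CX3CR1 effector-like cells were higher in cytolytic genes, lectin-like receptors, chemokines, effector factors and homing genes. Their list medians were lower for inhibitory and costimulatory receptors, exhaustion-associated factors and interferon-stimulated genes. Cytolytic granule genes had medians of 1.26 on day 8 and 1.34 on day 30, with 12 of 13 members higher in each. Gzma held 1341 against 11.3 CPM on day 8 and 7171 against 61.8 CPM on day 30, with log2 ratios of 6.89 (6.38 to 7.45) and 6.86 (6.57 to 7.17). Gzmb had ratios of 4.69 and 5.24, and Serpinb9 ratios of 2.33 and 2.12. Lectin-like receptors had medians of 1.75 and 4.07, and Klrc1 and Klrd1 were at 1.75 and 1.60 on day 8 and at 3.24 and 2.80 on day 30. Cytokines and chemokines had medians of 2.48 and 1.39, with Ccl5 at 4.12 and 3.61 and Ccl3 at 3.24 and 1.39. Their day 30 mean was 0.15, and with a total without ribosomal protein and mitochondrial genes their day 30 median was -0.09. Effector factors had medians of 0.99 and 1.25, with Id2, which represses E protein factors, at 2.91 and 1.79. Among homing genes (0.55 and 0.86), Ccr2 had ratios of 4.82 and 5.55 (3.66 to 8.61, from 2 UMIs in the progenitor-like cells), and the integrin gene Itgb2 ratios of 1.11 and 1.58. Cytokine receptors had medians of 0.95 and 0.38, outside the random range on day 8 alone, with Ifngr1 at 2.21 and 3.57.

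On the progenitor-like side, exhaustion-associated factors had medians of -0.94 and -1.72. Ikzf2, the gene of Helios, held 16.1 against 141 CPM on day 8 and 17.4 against 132 CPM on day 30, with ratios of -3.12 and -2.92. Eomes had ratios of -1.73 and -1.98, Batf -1.08 and -2.03, and Tox -1.18 and -0.84. Inhibitory receptors beyond the naming markers had medians of -0.52 and -1.45, with 3 of 5 and 3 of 6 members lower. The first of these was inside the random range with a total without ribosomal protein and mitochondrial genes (-0.34). Cd200 held 5.15 against 127 CPM on day 8. On day 30 it had 0 UMIs in the CX3CR1 effector-like cells against 123 CPM, so it was at least 70.5-fold lower. Costimulatory receptors had medians of -0.30 and -1.26, with Icos at -0.73 and -2.71 and Cd28 at -0.40 and -1.30, and the day 8 median was 0.04 at resolution 0.5. Interferon-stimulated genes had medians of -0.40 and -0.75, with Isg20 at -0.89 and -2.49, Ifi27l2a at -0.76 and -1.36 and Bst2 at -0.40 and -0.96. Memory and stem-like factors beyond the naming markers had medians of -0.25 and -0.39. The first was outside the random range but not with the lists among the features (-0.22), and the second was inside it but outside it in 5 alternatives (-0.43 to -0.76). Immediate early genes had medians of 0.01 and -0.33, with Fos at -1.01 and -0.73, and the day 8 median was -0.20 at resolution 0.5. Apoptosis (0.23 and 0.19), glycolysis (0.07 and -0.08), oxidative phosphorylation (0.10 and 0.11) and MHC class I (0.24 and 0.15) lists were inside the random range. The means were -0.08 for the day 8 immediate early list and 0.13 for the day 30 glycolysis list, opposite in sign to their medians. Progenitor-like cells had 37.1% and 37.5% of their UMIs from ribosomal protein genes, against 26.3% and 21.8% in CX3CR1 effector-like cells. With a total without those and the mitochondrial genes, the median ratio over all genes with at least 10 CPM moved by -0.28 on day 8 and -0.39 on day 30. Which genes reach that minimum changes with the total, so single ratios did not move by these amounts.

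The day 30 library also set exhausted-like against progenitor-like cells. Exhausted-like cells were higher in cytolytic genes (median 1.70, 11 of 13 members), cytokines and chemokines (3.46, 7 of 9), effector factors (1.29, 8 of 8) and cytokine receptors (0.83, 8 of 12). Gzma held 6006 against 61.8 CPM, a log2 ratio of 6.60 (6.31 to 6.91), and Gzmb and Gzmk had ratios of 5.04 and 2.95. Fasl held 182 against 4.65 CPM, a ratio of 5.29 (4.23 to 6.62). Ccl3 and Ccl4 had ratios of 3.56 and 3.46, and Ltb one of -0.97. Prdm1 held 99.1 against 1.99 CPM, a ratio of 5.64 (4.06 to 7.93), and Cd244 221 against 1.99 CPM, a ratio of 6.79 (5.23 to 9.08). Each of these rested on 3 UMIs in the progenitor-like cells. Progenitor-like cells were higher in memory and stem-like factors (-1.54), led by Satb1 at -4.02. Homing genes were split, with 6 of 13 members higher in the exhausted-like cells, 7 lower and Itgb1 at -2.49. Their median of -0.22 was below the random range, but inside it with the mean of per-cell CPM (-0.11).

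Interferon-stimulated genes (-0.37) and immediate early genes (-0.18) were lower in the exhausted-like cells too, with Bst2, Ifi27l2a and Jun at -0.87, -0.75 and -1.81. The interferon median was -0.04 at resolution 0.5, -0.06 without Scrublet calls and 0.10 without the deepest 5% of cells. The exhaustion-associated factors were just inside the random range at 0.51, and outside it in 6 of 7 alternatives (0.56 to 0.90). Of these, Maf and Nr4a2 were at 2.30 and 1.02, and Batf was at -0.93. Apoptosis regulators (0.53) and MHC class I genes (0.36) were inside it as well and outside it in 5 alternatives each, with Bcl2l11, which encodes the death factor Bim, at 1.99 and Tap2 at 0.93. Lectin-like receptors (0.40), inhibitory (0.37) and costimulatory receptors (0.33), glycolysis (0.03) and oxidative phosphorylation (0.19) lists were inside the random range. The means of the lectin-like receptor, costimulatory and glycolysis lists were below 0, at -0.03, -0.27 and -0.05. Cd200 and Tnfrsf4, which encodes OX40, were at -4.09 and -3.79. With a total without ribosomal protein and mitochondrial genes, the median ratio over all genes with at least 10 CPM moved by -0.36 in this contrast.

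**Figure D4:**
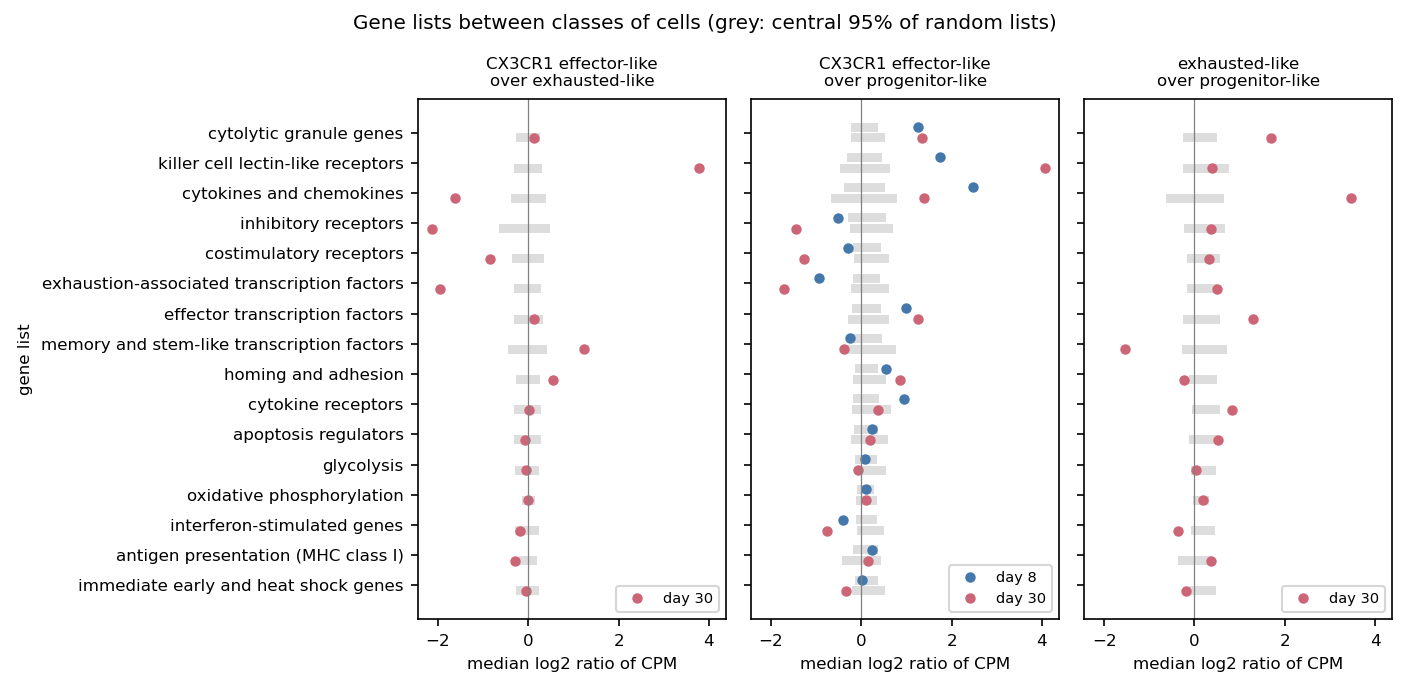
Median log2 ratio of CPM between classes for each program list on day 8 (blue) and day 30 (red), with the central 95% of matched random lists in grey. The lectin-like receptor list is at 3.79 over exhausted-like cells and at 4.07 over progenitor-like cells on day 30.

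A gate on Cx3cr1 transcripts asks the same question without clustering. It misses cells whose transcript was not captured, so its ratios are diluted. Of the thinned cells, 368 of 1872 on day 8 and 583 of 1750 on day 30 had a Cx3cr1 UMI. In both libraries these cells were higher in the other CX3CR1 effector markers (medians 0.91 and 2.01) and lower in the progenitor markers (-2.17 and -2.66). Exhausted markers were level on day 8 (median -0.01, mean 0.10) and lower on day 30 (-1.05). Zeb2 held 168 against 60.2 CPM on day 8 and 727 against 135 CPM on day 30, with log2 ratios of 1.49 (1.14 to 1.82) and 2.43 (2.24 to 2.62). Klra3 had ratios of 2.96 and 2.68, Klrg1 1.61 and 2.76, Il18rap 1.12 and 1.94, and Gzma 1.66 and 0.75. The kinase gene Sgk1, the glucose transporter gene Slc2a3 and Borcs7, Sun1 and Golm1 were higher on both days, between 0.72 and 1.83. Lower on both days were the progenitor genes Id3 (-3.79, -6.08 to -2.22, from 3 UMIs, and -4.01), Tcf7 (-2.93 and -2.01), Il7r (-2.33 and -3.60) and Slamf6 (-1.24 and -2.32). The same held for Tnfsf8, the CD30 ligand gene, at -1.93 and -2.72, Ltb at -1.11 and -2.36, Ctla4 at -1.29 and -2.04, and Isg15 at -1.04 and -1.52. Ms4a4c and Zfp36l1 had ratios of -0.88 and -1.18 on day 8 and of -2.13 and -0.80 on day 30.

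By list, Cx3cr1-detected cells were higher in lectin-like receptors (0.64 and 1.69), cytolytic genes (0.31 and 0.35) and effector factors (0.33 and 0.54). They were lower in exhaustion-associated factors (-0.40 and -0.98), costimulatory receptors (-0.48 and -0.99) and interferon-stimulated genes (-0.17 and -0.59). Of the 13 cytolytic members, 13 were higher on day 8 and 10 on day 30. Several of these medians were inside the random range in an alternative. With cells thinned to 1000 UMIs these were the day 30 cytolytic (0.09) and the day 8 effector factor (0.28) medians. Among cells not seen to cycle they were the day 30 cytolytic (0.29) and the day 8 effector factor (0.34), costimulatory (-0.30) and interferon-stimulated (-0.17) medians. Inhibitory receptors were level on day 8 (-0.02), but lower among cells not seen to cycle (-0.36), and lower on day 30 (-1.25). Across 2528 genes the gate ratios of the 2 days had a Pearson r of 0.53 and a Spearman rho of 0.39, and 64% of genes had the same direction. Genes are not independent replicates.

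A second gate took cells with a UMI of Slamf6 or Tcf7, 520 of 1872 on day 8 and 355 of 1750 on day 30. These cells were higher in the other progenitor markers (2.54 and 2.80) and in interferon-stimulated genes (0.60 and 0.49, 22 of 23 and 20 of 24 members). They were lower in CX3CR1 effector markers (-1.25 and -1.64), lectin-like receptors (-0.99 and -2.23), cytolytic genes (-0.81 and -1.23) and effector factors (-0.52 and -0.89). Id3, an inhibitor of E protein factors, held 133 against 12.9 CPM on day 8 and 156 against 19.7 CPM on day 30, with log2 ratios of 3.36 (2.81 to 3.94) and 2.99 (2.51 to 3.48). Dapl1 was at 3.53 and 2.59, the chemokine gene Cxcl10 at 2.61 and 2.48, Tnfsf8 at 2.35 and 2.74, and Il7r at 1.96 and 3.45. Rgs10, Cd200, Ms4a4c and Inpp4b were also higher on both days, between 1.31 and 2.81. Gzma was at -2.45 and -2.49, Klrg1 at -1.63 and -2.41, Gzmb at -1.24 and -1.89, Ccl4 at -1.28 and -1.93, Ccl3 at -1.23 and -1.93, and Cx3cr1 at -1.25 and -1.85. Zeb2, F2r, Sytl2 and Glrx were lower on both days as well. Exhausted markers had medians of -0.40 and -0.87, and among cells not seen to cycle the day 8 median was 0.43. The gate ratios of both days had an r of 0.65 and a rho of 0.54 across 2514 genes.

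Counting cells with UMIs of both genes gave a like picture. Cx3cr1 and Tcf7 were seen together in 7 cells on day 8, where independence would give 43.1, and in 23 on day 30, where it would give 62.0. Tcf7 and Slamf6 were seen together in 129 cells against 50.3, and in 87 against 27.2. Cx3cr1 and Gzma were seen together in 148 cells against 93.4, and in 415 against 318. Havcr2 and Tcf7 shared 5 cells on day 8 against 22.46, and 0 of 1750 cells on day 30 against 13.6. For Cx3cr1 and Pdcd1 the counts were 51 against 55.0 on day 8 and 79 against 132 on day 30. The shares in classes expected to be low in the gene also bear on these counts: up to 3.51% for Cx3cr1 and Tcf7, 1.11% for Havcr2, 9.06% for Gzma and 14.6% for Slamf6. The Slamf6 share came from day 8 CX3CR1 effector-like cells, which held 75.8 CPM of it, so it cannot be read as background alone.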

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

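The test on cycling cells was chosen after the result was seen, and the test on the exhausted-like cluster was recomputed on 3 genes, with a stricter bound, after its result was seen. Also chosen then was the minimum size (log2 0.3 and 50 CPM) for calling a gene opposite between the days. The differences between days listed here were not tested, since each day has 1 library.

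A few genes went opposite ways in the 2 libraries under the same contrast, with each interval on its own side of 0. Between cells with and without a Cx3cr1 UMI, the chemokine Ccl3 had log2 ratios of 0.45 (0.27 to 0.63) on day 8 and -1.14 (-1.32 to -0.97) on day 30. Ccl4 had ratios of 0.37 (0.22 to 0.52) and -0.57 (-0.67 to -0.47), and Gzmk ratios of 0.47 (0.10 to 0.84) and -0.67 (-0.91 to -0.43). The cytokine and chemokine list had medians of 0.35 on day 8, where its mean was -0.11, and -0.86 on day 30. With cells thinned to 1000 UMIs these medians were 0.22 and -0.30, both inside the random range. Among cells not seen to cycle the day 30 median was -0.11, also inside it. Between cells with and without a Slamf6 or Tcf7 UMI, Runx3 had ratios of 0.33 and -0.34. Between CX3CR1 effector-like and progenitor-like cells, the costimulatory receptor Tnfrsf18 had ratios of 0.57 and -0.83, and Maf ratios of 2.33 and -0.72.

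For Ccl3, Ccl4 and Gzmk the opposite directions were weighed. On day 30 the exhausted-like cluster held much of their RNA, and 7 of its cells had a Cx3cr1 UMI against 434 without. Leaving that cluster out, the median of the 3 genes on day 30 was 0.13 instead of -0.67, with Ccl3 at -0.05 (-0.27 to 0.16), Ccl4 at 0.55 (0.42 to 0.68) and Gzmk at 0.13 (-0.17 to 0.41). Leaving out a cluster rich in these transcripts and nearly without Cx3cr1 UMIs had to raise the ratios, and only Ccl4 then had an interval above 0, as all 3 had on day 8. Without that cluster none of the 3 genes had an interval below 0, so the lower day 30 ratios depended on its cells. Whether the exhausted-like cells account for the whole difference between the days stays open, since the intervals of Ccl3 and Gzmk then included 0. For Ccl3 and Ccl4 the values argue against the cells seen to cycle as the cause. Among cells not seen to cycle, Ccl3 was at 1.08 (0.62 to 1.53) on day 8 and -0.72 (-1.09 to -0.36) on day 30. Ccl4 was at 1.08 (0.70 to 1.45) and -0.37 (-0.56 to -0.17). Gzmk was at 0.71 (-0.35 to 1.70) and -0.42 (-0.93 to 0.07), and both of its intervals included 0. All of these intervals cover counting error only, not variation between cells or mice. The medians of the 3 genes were 1.08 and -0.42, a difference of 1.50. The stage of infection itself stays open and untested, because day and library coincide.

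Barcodes left out for carrying UMIs of at least 3 myeloid markers were 13 on day 8 (0.670% of barcodes) and 4 on day 30 (0.218%), above the 3 that a count of 0 allows. Of these, 12 of 13 and 4 of 4 also had at least 2 CD8 T cell markers. Their pooled RNA held Lyz2, a myeloid lysozyme gene, at 106 and 141 CPM and Cd3e at 452 and 636 CPM. The median totals were 7943 and 3567.5 UMIs, so the day 30 levels, pooled over 4 barcodes, rest on few UMIs. No explanation was tested for these barcodes.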

How the results depend on the processing

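Leaving out the deepest 5% of cells, and leaving out the small Ccr7-led clusters, were chosen after the data were seen. For the results that differ between settings the cause was not tested, except where stated.

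Between days, 255 of 264 alternative list values kept their reading, and 18 of 24 lists did so in each alternative run. A list kept its reading when both values lay outside the random range in the same direction. It also did so when both lay inside it, whatever their direction. With the mean of per-cell CPM the progenitor markers were at -0.31 instead of 0.12, the exhausted markers at 0.46 instead of 0.33, now outside the random range, and the interferon-stimulated markers and genes at 0.42 and 0.30, now inside it. Among cells not seen to cycle, effector factors (0.32) and interferon-stimulated genes (0.17) were inside it, and the replication gene Mcm5 was at 0.0513 instead of -0.52. With members of at least 50 CPM, which drops members, effector factors (0.22), replication genes (-0.0557) and interferon-stimulated genes (0.15) were inside it. Of 882 alternative gene values, 753 stayed within their counting interval, 128 moved and 1, that of Mcm5, changed sign, and 32 of 98 named genes stayed in each alternative. The largest shift of all ratios by another scaling was -0.0712.

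Without thinning, the day 30 to day 8 ratio of shares was 1.07 instead of 1.69 for Cx3cr1, 0.743 instead of 0.909 for Tcf7, 0.974 instead of 1.52 for Pdcd1 and 0.628 instead of 0.998 for Il7r. Day 8 cells were the deeper ones there, so depth adds to their shares. For Havcr2 the ratio was 0.953 at 1000 UMIs and 0.805 at 3000, instead of 0.713. Of 45 alternative shares, 39 kept their reading, and 4 of 9 genes did so in each alternative.

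Class shares moved in 17 of 42 alternatives, and 2 of 7 shares moved in none. At resolution 0.5 the CX3CR1 effector-like share was 50.8% on day 8 and 37.0% on day 30, and the proliferating-like share 19.97% and 15.6%. At resolution 1.2 the day 30 proliferating-like share was 10.1%. With lists among the features, CX3CR1 effector-like cells were 37.9% and 34.1%, and on day 30 progenitor-like cells 19.8% and proliferating-like cells 3.34%. With cycling genes out and cycle scores regressed out, CX3CR1 effector-like cells were 31.9% and 32%, and proliferating-like cells 26.7% and 3.95%. On day 30 CX3CR1 effector-like and proliferating-like cells were 32.3% and 5.01% without Scrublet calls, and 31.7% and 1.33% without the deepest 5% of cells.

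Between classes, 416 of 448 alternative list values kept their reading, and 52 of 64 lists did so in each alternative run. At resolution 0.5, CX3CR1 effector-like over progenitor-like cells gave costimulatory receptors 0.0417 and immediate early genes -0.20 on day 8, and memory factors -0.76 on day 30. Exhausted-like over progenitor-like cells gave exhaustion-associated factors 0.90, apoptosis regulators 0.71, MHC class I genes 0.44 and interferon-stimulated genes -0.0379. At resolution 1.2, memory factors in the former contrast were at -0.43, and exhaustion-associated factors and MHC class I genes in the latter at 0.78 and 0.41. With lists among the features, interferon-stimulated genes of CX3CR1 effector-like over exhausted-like cells were at -0.37 and memory factors over progenitor-like cells on day 8 at -0.22. Exhausted-like over progenitor-like cells then gave exhaustion-associated factors 0.65, apoptosis regulators 0.55 and MHC class I genes 0.35.

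Without Scrublet calls, memory factors of CX3CR1 effector-like over progenitor-like cells on day 30 were at -0.46. Exhausted-like over progenitor-like cells gave exhaustion-associated factors 0.77, apoptosis regulators 0.53, MHC class I genes 0.42 and interferon-stimulated genes -0.0562. Without the deepest 5% of cells these 4 were at 0.84, 0.77, 0.45 and 0.10, the memory factors at -0.65, and interferon-stimulated genes of CX3CR1 effector-like over exhausted-like cells at -0.40. With the mean of per-cell CPM, exhausted-like over progenitor-like cells gave exhaustion-associated factors 0.56 and homing genes -0.11. With a total without ribosomal protein and mitochondrial genes, CX3CR1 effector-like over progenitor-like cells gave inhibitory receptors -0.34 on day 8, and on day 30 memory factors -0.74 and cytokines -0.0904, as its members above the minimum differ. Apoptosis regulators of exhausted-like over progenitor-like cells were then at 0.20.

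Of 304 alternative gate values, 259 kept their reading, 20 passed out of the random range and 22 passed into it. A further 3 changed sign, with the main or the alternative value outside that range. In each alternative, 50 of 76 gate lists kept their reading. At 1000 UMIs, immediate early genes of the Cx3cr1 gate on day 8 were at 0.0392, and exhausted markers of the Slamf6 or Tcf7 gate on day 8 at -0.11. Among cells not seen to cycle those markers were at 0.43, and memory factors of that gate on day 30 at -0.0543. Thinning kept 1872 and 1750 cells, and depth limits detection of rare transcripts.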

Other observations

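Tests chosen after their results were seen are the comparison of like-named classes between the days, the test on cycling cells for the metabolic lists, and both tests on the small clusters. The test against progenitor-like cells was recomputed on the 8 fixed markers after its result on 5 chosen genes was seen, where it had argued against that kind.

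Within the CX3CR1 effector-like cells the day 30 library was higher in lectin-like receptors, CX3CR1 effector markers and effector factors, and lower by list median in inhibitory and costimulatory receptors and interferon-stimulated genes. The 2 clusters were found separately, 1 per library, and the day 8 cluster was less set apart from its library. Cx3cr1 was at 209 CPM in it against 125 in the whole day 8 library, and at 826 against 292 on day 30. The ratios therefore do not separate the day from how sharply each cluster was drawn. List medians between the clusters, day 30 over day 8, were 1.31 for lectin-like receptors (random lists -0.43 to 0.35), 1.62 for CX3CR1 effector markers and 0.82 for effector factors. S1pr5 went from 20.2 to 354 CPM, Zeb2 from 130 to 887 CPM and Cx3cr1 from 209 to 826 CPM, with log2 ratios of 4.13, 2.77 and 1.99. Klra9 and Klre1 had ratios of 6.07 and 4.05, and the factor Klf3 one of 2.36. Cxcr3 went from 225 to 17.4 CPM, a ratio of -3.69, and Il7r, Ltb, Ctla4 and Lag3 had ratios of -3.22, -2.96, -2.66 and -1.96. Inhibitory receptors had a median of -0.71, with 6 of 9 members lower, and costimulatory receptors one of -0.76, with 5 of 7 lower. Against this, Cd244 went from 7.89 to 50.5 CPM, a ratio of 2.68, and Entpd1 had a ratio of 1.39. Exhausted markers had a median of -0.86, and interferon-stimulated genes one of -0.41, with Zbp1 at -1.34. The cytolytic list was inside the random range at 0.20, with Gzma at 2.42. Also inside it were exhaustion-associated factors (median 0.13, 6 of 9 higher) and cytokines and chemokines (-0.04, 3 of 6 higher). Over all cells of the libraries these 2 lists had medians of 1.27 and 0.61, outside the random range.

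Progenitor-like cells differed between the libraries in other genes. Cytokines and chemokines had a median of 1.34 with 7 of 7 members higher on day 30, among them Xcl1, from 71.5 to 667 CPM (3.22), and Ccl4 (2.10). Exhaustion-associated factors had a median of 0.35, with Maf at 2.47, Eomes at 1.50 and Nr4a2 at 1.38, and immediate early genes one of 0.50, with Ier5 at 2.43 and Dusp1 at 2.08. Interferon-stimulated genes had a median of 0.20 (random lists -0.24 to 0.17) with 16 of 24 members higher, against 5 of 22 in the CX3CR1 effector-like cells. The difference between the classes was not tested. Ifngr1, Il18r1 and Lef1 were lower, at -1.98, -1.63 and -0.997.

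Lower glycolysis and oxidative phosphorylation lists on day 30 (-0.38 and -0.41) were weighed against 3 explanations. Among cells not seen to cycle they were at -0.26 and -0.32, still below the random range. Fewer cycling cells may account for part of the difference. Cycling cells whose cycle transcripts were missed can be in this set, so cycling as the whole cause is not excluded. Leaving the 10 genes with the most UMIs out of the total moved each ratio by 0.0688, less than either median. Within the CX3CR1 effector-like cells the lists were at -0.28 and -0.39, and within the progenitor-like cells at -0.52 and -0.37, all below the random range, which argues against another mix of these clusters as the whole cause. The stage of infection stays open and untested, as do depth and handling, which coincide with the day.

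A small cluster led by Ccr7, Il6ra and Treml2 held 29 cells on day 8 and 39 on day 30. Naive T cells that passed the sort are a candidate source, although sorting on CD44 and gp33 binding would remove them. The 10 naive T cell genes had median log2 ratios over all other cells of 1.28 and 2.38, with Ccr7 at 4.17 and 4.55, but at least Tcf7, Il7r, Lef1 and Ccr7 are also expressed by progenitor cells. The 10 effector and memory genes were lower, with medians of -2.28 and -4.07. Ccl5 was still at 4904 and 1442 CPM, against 13449 and 35853 CPM in the other cells, and Cd44 at 80.4 and 22.05 against 78.4 and 53.1. On day 8 the values lay between those set for and against naive cells, so naive cells and other cells with low effector transcripts cannot be told apart. Cells of the progenitor-like kind stay open too. Against the progenitor-like cells, the 8 fixed progenitor markers had medians of -0.60 and -0.58, but they went both ways. Ccr7 (1.96 and 2.63), Il7r (1.98 and 0.45) and Lef1 (0.77 and 1.93) were higher, and Slamf6 (-2.48 and -2.04), Id3 (-2.28 and -1.38) and Xcl1 (-2.15 and -4.07) were lower, each with an interval on its own side of 0. A biological explanation from the design, such as the day, was not tested for this cluster.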
